A study of Mus musculus with 10 samples.

How the data were processed

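RNA was sequenced from the blood of C57/BL6J mice, the cell type being given as leukocyte in the labels. Each of the 10 libraries was made from RNA of the blood of 3 mice of a group, and every group had a single library. The groups were a control at 0 h (Con), sleep deprivation (SD) for 6, 12, 24 and 48 h, and a sleep restriction method reported earlier (SASD) for 6, 12, 24, 48 and 120 h. How SD and SASD were carried out, and the hour of the day at which blood was taken, are not given in the sources used here.

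Per the submitters' processing notes, the authors trimmed reads with Trimmomatic 0.39 and aligned them to mm10 with STAR 2.7.9a. Per the file headers, the authors counted read pairs over exons per gene with featureCounts 2.0.3. Their annotation was the mouse one of a 10x Genomics reference package. Gene positions, gene types and exon lengths were read here from GENCODE release 21 of the mouse series, which may differ from it. No strand option was set, and reads that mapped to several places or overlapped several genes were not counted. Antisense and overlapping genes were therefore uncertain, and so were genes with similar copies that may share reads, which was not measured: Hba-a1 with Hba-a2, Hbb-bs with Hbb-bt, Csf2rb2 with Csf2rb, Ifitm1 with Ifitm2, Wfdc17 with Wfdc21, Mrgpra2b and Gm14548. The deposited values were raw counts for 32285 genes, of which 32158 had a symbol in the reference used here and 127 did not. All 10 count columns matched a sample label. Total counts per library ran from 7825120 to 27501393.

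From these counts TMM factors were computed in edgeR 4.0.16 (R 4.3.3), and genes with a mean count of at least 10 over the libraries of a fit were tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. SD against SASD was fitted on the 8 libraries at 6, 12, 24 and 48 h with time as a block (3 residual degrees of freedom), so that the p-value asked whether a difference was steady over the 4 times. Trends were slopes on the log2 of 1 plus hours divided by 6, fitted on Con and the 4 SD libraries (3 residual degrees of freedom) or on Con and the 5 SASD libraries (4). The difference between the trends was the SD slope minus the SASD slope with a shared Con over 9 libraries (6 residual degrees of freedom). With 1 library per group the p-values measured the spread between these pooled libraries and times, part of which is technical. Standard errors were taken from the log2 estimate and its F value. Counts were also simulated for the real genes and library sizes, with changes equal at all 4 times or, for trends, on a straight line. On these the edgeR fit of SD against SASD recovered 75.0% of genes changed 2-fold and 96.0% of those changed 4-fold. The same shares were 4.21% and 51.6% for the SD trend over its time range and 0% and 37.1% for the SASD trend. They were 13.3% and 67.7% for the difference of trends. False calls numbered 16, 11, 7 and 10 beside 95 to 100 changed genes of each size, more than 0.05 of all calls in each fit. These shares do not cover changes that vary between times. In the real fit of SD against SASD, Mpo at a log2 ratio of 5.56 ± 1.00 was not called (edgeR adjusted p = 0.310).

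Single libraries were compared by the log2 ratio of TMM-scaled CPM (counts scaled to equal library size) with a prior count of 2 for ranking, list medians and counts of 2-fold genes, among genes with a mean count of at least 25 in the pair. Printed ratios of single genes used no prior count. Their 95% counting intervals came from an exact conditional binomial (Clopper-Pearson), as did those of shares of counts (scipy 1.17.1, Python 3.11.15). The intervals cover counting error only. For correlations of changes against the shared Con library, 50 simulations of unchanged groups gave the value that the shared control produces alone.

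Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 29 lists with at least 5 measured genes. They covered mature neutrophils, neutrophil granules and precursors, monocytes, B cells, T cells, NK and cytotoxic cells, platelets, erythroid cells, eosinophils and basophils, and dendritic and plasma cells. Others held cytokines and chemokines, cytokine receptors and decoys, the NF-kB and inflammasome response, interferon-stimulated genes, MHC class II, glucocorticoid-induced genes, the circadian clock, heat shock and the unfolded protein response, oxidative stress, proliferation, immediate early genes, prostaglandin synthesis and fatty acid use. The rest held glycolysis and hypoxia, neutrophil recruitment and adhesion, coagulation and complement, ribosomal proteins, mitochondrially encoded genes and replication-dependent histones. Of 649 list entries 642 matched the table; Ahsp, Mx1, Mx2, Ddit3, Aldoa, mt-Rnr1 and mt-Rnr2 were not analysed here. A list of Y-linked genes and Xist had only 4 measured genes, under the minimum of 5, and was not tested; Ddx3y lay between 131 and 185 CPM in all 10 libraries. For single libraries a list's median log2 ratio was placed among 10000 random lists of the same size matched on mean expression in 10 bins.

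Groups, tests, gene lists and alternatives were fixed before the data were examined. So was the rule for named genes: for each test the 12 largest changes past the threshold per direction, for 48 h and 120 h ratios the 10 highest and lowest genes with a mean count of at least 100 (predicted genes, pseudogenes and receptor V segments left out), and from each list the 3 most abundant members and the 3 with the largest change. A few genes that met this rule are not reported here. Set against these choices, also beforehand, were RLE size factors, no count minimum, a mean count of at least 50, DESeq2 1.42.0, limma-trend, haemoglobin and mitochondrial genes left out of library sizes, no time block, linear or ranked hours, each time left out in turn, a prior count of 0.5 and a mean count of at least 100 for ratios.

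Added after seeing the data were a split of the libraries, the fits that use it, and the test of gene lists on the difference of trends. The split was read from the share of 1134 olfactory receptor genes with a count after thinning each library to 7825120 counts, and it set Con, SD 48 h and SASD 48 h (3 libraries) against the other 7. A first rule, the largest gap in the number of genes detected, had set only Con apart and was replaced by the largest gap of that share on a log scale. Fits were repeated with the split as a term and without Con and the 48 h libraries.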

Results

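Blood leukocyte transcriptomes were followed over time in mice kept awake by SD and in mice under SASD, with Con as the 0 h reference. Total counts were 27501393 in Con, 10926554, 10445615, 11141786 and 13927134 in SD 6, 12, 24 and 48 h, and 11082847, 9559914, 7825120, 24818986 and 10110229 in SASD 6, 12, 24, 48 and 120 h. Each group was a single pool of 3 mice, so ratios between single libraries had no replicate check.

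The libraries fell into 2 sets that did not part SD from SASD, the libraries of each shared time lying in the same set. Haemoglobin genes, which mark red cells and reticulocytes, took 0.727% of the counts in Con, 0.316% in SD 48 h and 0.275% in SASD 48 h, and 3.57% (SASD 120 h) to 6.96% (SASD 24 h) in the other 7 libraries. The exact Clopper-Pearson 95% intervals of these shares reached at most 0.0178 percentage points to either side. Olfactory receptor genes, which have no known role in leukocytes, had a count for 53.1%, 19.8% and 38.4% of 1134 genes in Con, SD 48 h and SASD 48 h at equal depth, and for 2.38% to 4.32% in the other 7. Ratios of SD over SASD at 1 time never crossed this split, whereas ratios over Con crossed it at 6, 12, 24 and 120 h.

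**Figure D1:**
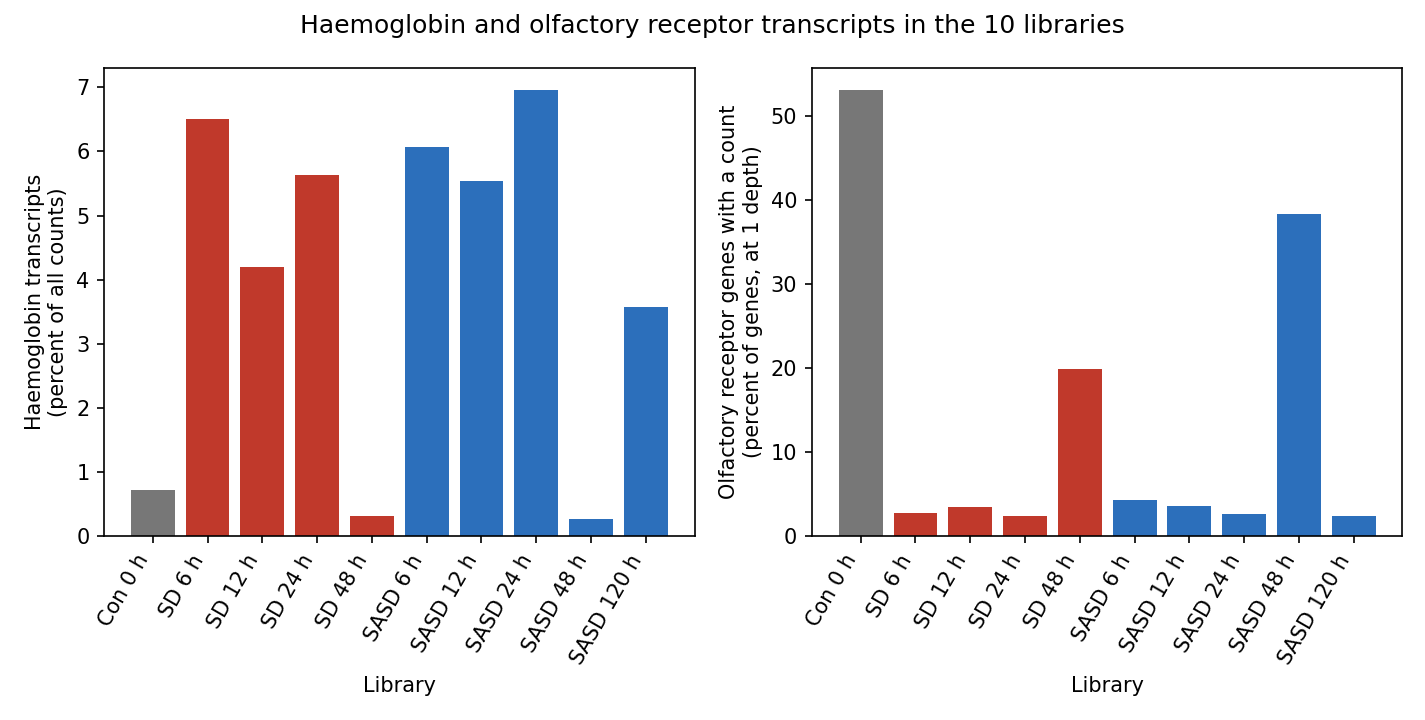
Share of counts from haemoglobin genes (left, percent) and share of 1134 olfactory receptor genes with a count at equal depth (right, percent) in each of the 10 libraries. Con, SD 48 h and SASD 48 h lie at 0.275% to 0.727% for haemoglobin and at 19.8% to 53.1% for olfactory receptor genes, the other 7 at 3.57% to 6.96% and 2.38% to 4.32%.

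The first comparison asked how leukocytes differed between SD and SASD at the 4 shared times. Transcripts of mature neutrophils stood higher under SD. S100a8 and S100a9, which encode the subunits of calprotectin, had log2 ratios of SD over SASD of 1.78 ± 0.30 and 1.77 ± 0.33 (SE over 4 times). Il1r2, the decoy receptor of interleukin-1, gave 1.79 ± 0.50, Il1b, the cytokine itself, 1.38 ± 0.26, Cxcr2, a receptor for neutrophil-attracting chemokines, 1.19 ± 0.27, and Lcn2, a granule lipocalin, 1.87 ± 0.51. B cell transcription factor genes lay lower under SD, with -0.51 ± 0.18 for Pax5 and -0.44 ± 0.19 for Ebf1. No gene passed on its own: edgeR called 0 of 13370 genes, with 1082 at an unadjusted p under 0.05 where 668.5 were expected by chance, limma called 0 and DESeq2 173 (169 higher, 4 lower under SD). The edgeR adjusted p was 0.310 for S100a8, S100a9, Il1b and Cxcr2, 0.383 for Il1r2, 0.379 for Lcn2, 0.548 for Pax5 and 0.608 for Ebf1. Without the 6 h libraries edgeR called 237 genes, 236 of them higher under SD, and with no count minimum 389.

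By list, the camera test placed 15 of 29 lists past the threshold, and none (0) with an estimated correlation. No list passed fry, the lowest adjusted p being 0.403, that of mature neutrophils among others. Mature neutrophil genes were higher as a group (adjusted p = 1.05e-19, and adjusted p = 0.568 with an estimated correlation), with 22 of 22 members above 0, 0 called over all genes and 22 adjusted over the list alone. Neutrophil granule and precursor genes (9.45e-08, and adjusted p = 0.568 with an estimated correlation) had 0 calls over all genes and 13 of 16 adjusted over the list alone, Mmp8, a collagenase, standing at 1.43 ± 0.41. Genes of neutrophil recruitment and adhesion, 11 of 19 of which belong to other lists as well and so carry part of the same signal, were higher (1.01e-07, and adjusted p = 0.568 with an estimated correlation, 12 of 19 adjusted over the list alone), among them the formyl peptide receptor gene Fpr2 at 1.61 ± 0.39. Cytokine receptors and decoys followed (4.55e-08, and adjusted p = 0.568 with an estimated correlation, 8 of 25 adjusted over the list alone), with Il1rap, the coreceptor of interleukin-1, at 1.41 ± 0.23 and Csf3r, the G-CSF receptor, at 0.79 ± 0.22. The camera adjusted p was 0.0105 for cytokines and chemokines (adjusted p = 0.709 with an estimated correlation, 2 of 23 adjusted over the list alone), where Osm, oncostatin M, stood at 1.04 ± 0.19. This call was lost without 12 h (0.163) and without 24 h (0.0865).

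Stress-responsive lists moved with these. The libraries were bulk RNA of blood leukocytes, so values of all lists describe the mixture of cells. Whether the shares of cell types or the levels per cell changed was not tested for these lists. Glucocorticoid-induced genes were higher under SD (adjusted p = 9.42e-07, and adjusted p = 0.568 with an estimated correlation), with 22 of 22 members above 0 and 2 adjusted over the list alone, such as Dusp1, a MAP kinase phosphatase, at 1.33 ± 0.27. Of this list 6 of 25 genes also belong to other lists and may carry part of the same signal, such as Il1r2, a mature neutrophil list gene. The same holds for 4 of 25 cytokine receptor, 3 of 28 NF-kB and 3 of 24 immediate early genes. The NF-kB and inflammasome response (1.18e-04, 10 of 27 adjusted over the list alone), immediate early genes (1.06e-04, 5 of 24), glycolysis and hypoxia (6.54e-05, 1 of 24) and oxidative stress (0.0105, 4 of 23) were higher, each at adjusted p = 0.568 with an estimated correlation. Cd14, the lipopolysaccharide coreceptor, stood at 2.22 ± 0.52, Socs3, a brake on cytokine signalling, at 1.49 ± 0.33, Fos at 1.17 ± 0.20, Slc2a1, a glucose transporter, at 0.75 ± 0.14 and Gsr, glutathione reductase, at 0.81 ± 0.20. B cell genes (8.26e-05, and adjusted p = 0.691 with an estimated correlation, 0 of 18 above 0), NK and cytotoxic genes (0.00786, and adjusted p = 0.568) and mitochondrially encoded genes (0.00279, and adjusted p = 0.568) were lower. Ribosomal proteins (8.26e-05, and adjusted p = 0.785 with an estimated correlation) and T cell genes (0.0461, and adjusted p = 0.859) were higher. Leaving out the 48 h libraries ended the calls of B cells (0.0566), glycolysis (0.0654), oxidative stress (0.314) and ribosomal proteins (0.141) and turned that of T cells (0.274). The T cell call also ended without 6 h (0.0659), that of NK cells without 6 h (0.171) or 12 h (0.0625), and that of mitochondrially encoded genes without 12 h (0.0809).

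The other 14 lists did not pass. Camera adjusted p-values were 0.472 for monocytes, 0.0733 for platelets, 0.749 for erythroid genes, 0.964 for eosinophils and basophils, 0.736 for dendritic and plasma cells, 0.161 for interferon-stimulated genes, 0.0771 for MHC class II and 0.736 for the circadian clock. They were 0.482 for heat shock and the unfolded protein response, 0.161 for proliferation, 0.844 for prostaglandin synthesis, 0.736 for fatty acid use, 0.119 for coagulation and complement and 0.482 for replication-dependent histones. Within the clock list, Per2 stood at 0.98 ± 0.15 and Nfil3, a repressor that also acts in lymphocyte development, at 1.13 ± 0.28, and 2 of 21 members passed when adjusted over the list alone.

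The difference opened after 6 h. The median log2 ratio of SD over SASD of mature neutrophil genes was 0.12 at 6 h, 1.47 at 12 h, 1.26 at 24 h and 2.16 at 48 h, and that of granule and precursor genes -0.06, 0.58, 0.97 and 3.91. Among random lists matched on expression the mature neutrophil median lay at the 98.6th percentile at 6 h and the granule median at the 37.4th, and both lay at the 100th at the later times. Monocyte genes ran -0.37, 0.19, 0.77 and -0.25, B cell genes 0.12, -0.11, -0.23 and -0.48 and T cell genes 0.00, -0.18, 0.06 and 0.60. Platelet genes moved as far as the neutrophil genes at 24 h and the other way, at -0.32, -0.16, -1.28 (15 of 17 at least 2-fold lower) and 0.91. Erythroid genes ran 0.15, -0.32, -0.70 and 0.52. Genes at 2-fold or more between the methods numbered 116 at 6 h (12 higher under SD), 331 at 12 h (320 higher), 788 at 24 h (432 higher) and 727 at 48 h (522 higher). With a mean count of at least 100 they numbered 17, 216, 497 and 379. The 21 pairs among the 7 libraries other than Con and 48 h, these 6, 12 and 24 h pairs included, had a median of 350. On the side of the 48 h pair, Con differed from SD 48 h at 1676 genes and from SASD 48 h at 1202.

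**Figure D2:**
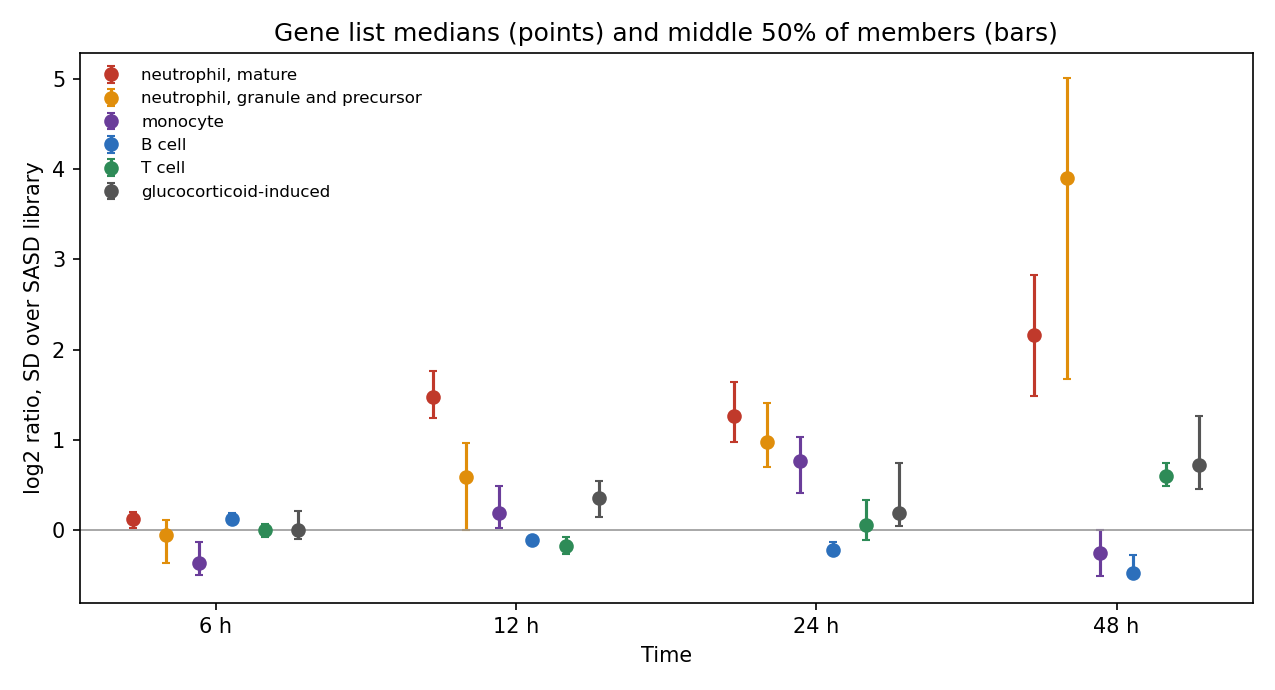
Median log2 ratio of SD over SASD at 6, 12, 24 and 48 h for 6 gene lists, with bars for the middle 50% of the members. The mature neutrophil median goes from 0.12 at 6 h to 2.16 at 48 h and the granule and precursor median from -0.06 to 3.91, while the B cell median goes from 0.12 to -0.48.

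At 48 h, where both libraries lay on the same side of the split, the highest ratio of SD over SASD was that of Prok2, a prokineticin gene, with 339 counts in SD and 3 in SASD (219.6, 95% counting interval 74.5 to 1070.4). Members of the granule and precursor list among the 10 highest were Camp, the cathelicidin precursor gene, at 100.5 (66.0 to 160.9), Mpo, myeloperoxidase, at 85.7 (46.2 to 180.0), Ngp, neutrophilic granule protein, at 63.1 (55.0 to 72.7), Ltf, lactoferrin, at 30.6 (27.1 to 34.6) and Itgb2l at 26.4 (16.9 to 43.3). The others were Lipg at 67.3 (33.7 to 157), Ston1 at 25.6 (15.8 to 43.9), the neutrophil marker gene Ly6g at 23.5 (18.05 to 30.97) and Crispld2 at 18.7 (15.7 to 22.4). Lower in SD 48 h were Plet1 at a ratio of 0.0874 (0.0460 to 0.152), Lpl, lipoprotein lipase, at 0.270 (0.219 to 0.331), Siglec1, a sialic acid receptor gene, at 0.398 (0.311 to 0.506) and Slamf8 at 0.402 (0.288 to 0.551). Muc4, Fcamr, BC035044, Slc5a3, Cacna1d and Ino80dos completed the 10 lowest, at 0.255 to 0.398. These lower ratios were not separated from background. Olfactory receptor genes were detected at 19.8% in SD 48 h and at 38.4% in SASD 48 h at equal depth.

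The SD trend asked which transcripts changed steadily with the hours awake. Prok2 rose by 2.54 ± 0.19 (SE, 5 libraries) on the log2 scale for each doubling of 1 plus hours divided by 6, and Upp1, uridine phosphorylase, by 1.71 ± 0.12. Mmp8 rose by 0.99 ± 0.09, Anxa1, annexin A1, which limits neutrophil adhesion, by 0.92 ± 0.08, Fpr1 by 0.83 ± 0.08 and Cxcr1, an interleukin-8 type receptor, by 0.82 ± 0.08. Prok2 went from 0.122 CPM in Con through 0.286, 1.41 and 8.45 to 23.2 CPM at 48 h. EdgeR called 18 of 14562 genes, all rising, with 1515 at an unadjusted p under 0.05. The adjusted p of the 12 named genes was 0.0355 to 0.0411. The others were Wfdc17 (1.71 ± 0.15), C1rl (1.32 ± 0.11), Ifitm1 (1.26 ± 0.12), 9830107B12Rik (1.24 ± 0.08), Csf2rb2 (1.03 ± 0.09) and Gm14548 (0.78 ± 0.06), of which Wfdc17, Ifitm1, Csf2rb2 and Gm14548 may share reads with copies.

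The size of this set depended on the model. No gene was called without the SD 6 h, 12 h or 24 h library (0 each) or with hours on a linear scale (0), whereas 53 were called without Con (45 rising, 8 falling) and 511 without SD 48 h (308 rising, 203 falling). The edgeR adjusted p of Prok2 was 0.172 without SD 6 h, 0.0611 without 12 h, 0.1997 without 24 h and 0.346 with linear hours. Its slope stayed between 2.41 and 2.83 whichever library was left out. DESeq2 called 431 (409 rising), limma 50 and ranked times 65. With the split as a term, added after seeing the data, edgeR called 796 (629 rising), all 18 among them, and without Con and SD 48 h 314 (297 rising).

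Of 29 lists 19 passed camera for the SD trend, none (0) with an estimated correlation, and no list passed fry. Mature neutrophil genes rose together (adjusted p = 8.80e-25, and adjusted p = 0.254 with an estimated correlation; fry 0.0562), with 22 of 22 slopes above 0, 1 called over all genes and 21 adjusted over the list alone. S100a8 had a slope of 0.87 ± 0.11, S100a9 0.92 ± 0.12, the resistin-like gene Retnlg 1.03 ± 0.14 and Ly6g 1.59 ± 0.20, at edgeR adjusted p-values of 0.0616, 0.0707, 0.0707 and 0.0651. Granule and precursor genes rose (1.14e-12, and adjusted p = 0.254 with an estimated correlation), 1 over all genes and 15 of 16 adjusted over the list alone, with 1.26 ± 0.15 for Lcn2, 1.72 ± 0.35 for Ngp and 1.89 ± 0.50 for Camp. Without SD 48 h the Camp slope was -0.21, its level being 1.56 CPM in Con, 0.859 to 1.21 from 6 to 24 h and 77.8 at 48 h. Recruitment and adhesion genes (7.49e-15, and adjusted p = 0.254 with an estimated correlation, 1 and 11 of 19) included the leukotriene B4 receptor gene Ltb4r1 at 0.92 ± 0.11 and Cd177 at 0.87 ± 0.15. Cytokine receptors and decoys (8.70e-11, and adjusted p = 0.268, 0 and 10 of 25) had Il1r2 at 0.95 ± 0.19 and Il1rap at 0.85 ± 0.16. Cytokines and chemokines passed at 0.0264 (adjusted p = 0.415 with an estimated correlation, 5 rising and 1 falling of 25 adjusted over the list alone), with Il1b at 0.71 ± 0.21, and this call was lost without SD 6 h (0.0936) and without SD 48 h (0.293).

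Monocyte genes rose (1.97e-06, and adjusted p = 0.389 with an estimated correlation, 6 of 20 adjusted over the list alone), with slopes of 0.76 ± 0.10 for Tgfbi and 0.69 ± 0.18 for the chemokine receptor gene Ccr2. Glycolysis and hypoxia (8.70e-11, and adjusted p = 0.254, 1 over all genes and 11 of 24) held Egln3, an oxygen-sensing prolyl hydroxylase, at 0.68 ± 0.07 and Slc2a1 at 0.41 ± 0.09. Coagulation and complement (1.29e-04, and adjusted p = 0.254, 6 of 22) held C3 at 0.60 ± 0.14 and the anaphylatoxin receptor gene C5ar1 at 0.58 ± 0.12. B cell genes had falling slopes as a list (1.57e-07, and adjusted p = 0.254 with an estimated correlation, 0 of 18 slopes above 0), though 0 were called over all genes and 0 adjusted over the list alone. The IgE receptor gene Fcer2a stood at -0.25 ± 0.07 and Cd22 at -0.20 ± 0.06. MHC class II genes had falling slopes as a list (0.00985, and adjusted p = 0.541), a call lost without Con (0.115), SD 6 h (0.0713) or SD 24 h (0.0822). T cell genes (3.69e-05, and adjusted p = 0.530 with an estimated correlation), glucocorticoid-induced genes (4.39e-05, and adjusted p = 0.426), the NF-kB response (4.39e-05, and adjusted p = 0.389), immediate early genes (6.53e-05, and adjusted p = 0.530) and oxidative stress (2.08e-05, and adjusted p = 0.368) passed with rising slopes and lost their calls without Con (0.745, 0.302, 0.0695, 0.426 and 0.255). Fos had a slope of 0.92 ± 0.19 and Hmox1, haem oxygenase, 0.51 ± 0.12.

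The remaining lists with rising slopes were ribosomal proteins (3.20e-04, and adjusted p = 0.588 with an estimated correlation), proliferation (0.00829, and adjusted p = 0.588), heat shock (0.0264, and adjusted p = 0.588) and interferon-stimulated genes (0.00609, and adjusted p = 0.628). Ribosomal and proliferation slopes turned without SD 48 h (0.454 and 0.341), and interferon slopes turned without Con (0.0347) and did not pass without SD 24 h (0.0852). The heat shock call was lost without Con (0.144) and without SD 24 h (0.161). Within the interferon and proliferation lists Rsad2 and Ube2c, the latter chosen after its values were seen, followed the haemoglobin share: Rsad2, or viperin, was at 91.9 to 119.8 CPM in Con and both 48 h libraries and at 653 to 3369 in the other 7, and Ube2c, a mitotic ubiquitin ligase partner, at 2.36 to 5.68 against 19.2 to 79.0. The lists as a whole did not. The proliferation median over Con was 0.64 in SD 48 h, and 0.11, -0.01 and -0.17 in SD 6, 12 and 24 h. Interferon medians over Con were 0.54 in SD 48 h and 0.55 in SASD 48 h, within the 0.38 to 0.85 of the other 7. Haemoglobin and olfactory receptor shares divided the SD libraries as Rsad2 and Ube2c did, Con and SD 48 h from the rest. With a term for that split 21 of 22 mature neutrophil and 16 of 16 granule genes were called as rising over all genes, where 1 and 1 were called without it. The lists did not pass with that term and an estimated correlation (camera adjusted p = 0.498 and 0.367).

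**Figure D3:**
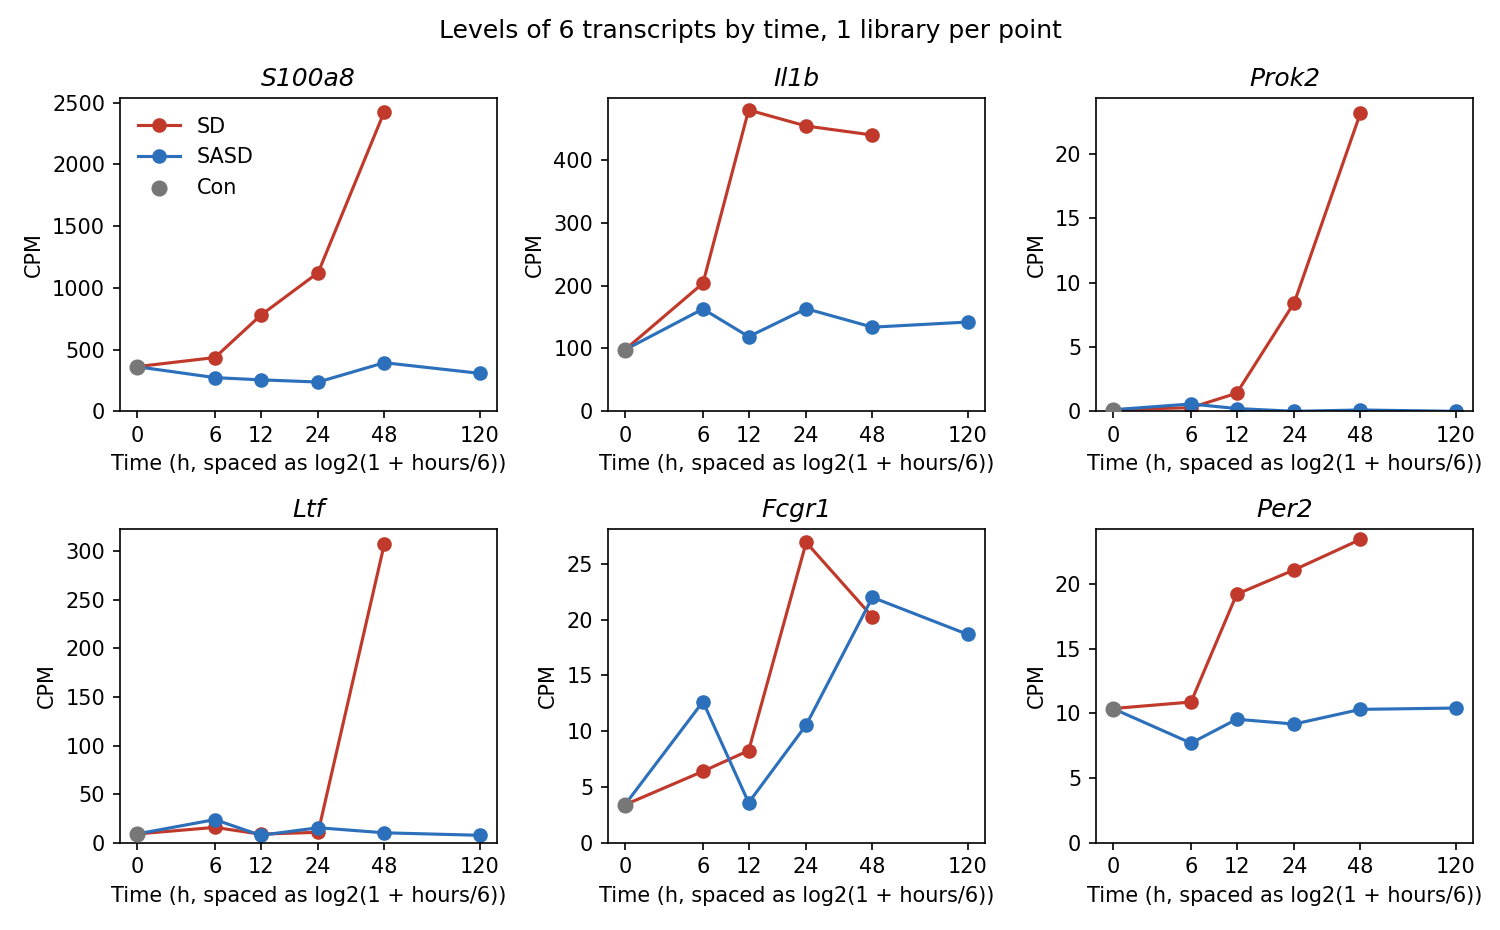
Level in CPM of S100a8, Il1b, Prok2, Ltf, Fcgr1 and Per2 by hours of SD or SASD, 1 point per library, with Con at 0 h. S100a8 goes from 362 in Con to 2427 at SD 48 h against 394 at SASD 48 h, and Ltf stays between 8.66 and 15.7 up to SD 24 h and lies at 307.8 at SD 48 h.

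The SASD trend asked the same of the sleep restriction method, over 120 h. Genes of heat shock and the unfolded protein response had rising slopes as a list (camera adjusted p = 1.55e-10, and adjusted p = 0.331 with an estimated correlation), with 24 of 26 slopes above 0, 0 called over all genes and 1 adjusted over the list alone. Hspa8, a constitutive chaperone, had a slope of 0.22 ± 0.08 (SE, 6 libraries) and went from 741 CPM in Con to 1287 at 120 h, Hsp90ab1 had 0.15 ± 0.06 and the inducible Hspa1b 0.65 ± 0.11. Monocyte genes had rising slopes as a list (2.57e-08, and adjusted p = 0.528 with an estimated correlation), 20 of 20 lying above 0. Of these 0 were called over all genes and 0 adjusted over the list alone. Fn1, fibronectin, stood at 0.37 ± 0.21 and Ccr2 at 0.37 ± 0.15. Neutrophil lists did not pass, at 0.426 for mature and 0.538 for granule genes.

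No single gene passed: edgeR called 0 of 14602, with 443 at an unadjusted p under 0.05 where 730.1 were expected by chance, and limma and DESeq2 called 0 each. Without SASD 48 h 1 gene was called. With the split as a term edgeR called 0 and DESeq2 113 (44 rising, 69 falling). Fits this small recovered 0% of 2-fold changes in simulation, so changes of that size were not detectable one gene at a time.

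Camera placed 9 of 29 lists past the threshold, 5 without SASD 6 h, and none (0) with an estimated correlation. No list passed fry, the lowest adjusted p being 0.149 for heat shock and for proliferation. Interferon-stimulated genes (1.27e-07, and adjusted p = 0.575 with an estimated correlation), the NF-kB response (3.20e-04, and adjusted p = 0.437) and immediate early genes (3.20e-04, and adjusted p = 0.575) had rising slopes, and each call was lost without Con (0.328, 0.170 and 0.542). Among their members Oas1a had 0.23 ± 0.11, Bcl3 0.19 ± 0.06 and Atf3 0.22 ± 0.06. B cell genes (0.0220, and adjusted p = 0.768) and MHC class II (0.0334, and adjusted p = 0.768) had rising slopes too. The B cell call was lost without SASD 6 h (0.113) or 120 h (0.909), and the MHC call without 6 h (0.113), 12 h (0.0556), 48 h (0.146) or 120 h (0.785). Platelet genes (0.0247, and adjusted p = 0.875) and proliferation (0.0336, and adjusted p = 0.437) had falling slopes. The platelet call was lost without SASD 6 h (0.139), 12 h (0.140), 48 h (0.784) or 120 h (0.177), and the proliferation call without any single library but SASD 24 h (0.0835 to 0.180). With the split as a term 17 of 17 platelet and 11 of 17 erythroid genes fell when adjusted over the list alone. Likewise 15 of 26 heat shock and 8 of 20 monocyte genes rose. Of all these 0 were called over all genes, and each list stood at a camera adjusted p of 0.581 with that term and an estimated correlation. The platelet genes lay lowest in SASD 48 h, such as Ppbp at 575 CPM against 3392 at 24 h, and so did haemoglobin at 0.275%. Glucocorticoid-induced genes did not pass (0.171), Fkbp5 standing at -0.38 ± 0.12 and Ddit4 at -0.41 ± 0.19.

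The difference between the trends asked directly whether a slope was higher under SD than under SASD over 48 h. The 58 genes called by edgeR, of 14138 tested, were all steeper under SD, 9 of the 22 mature neutrophil genes and 1 of the 16 granule and precursor genes among them. The largest differences were those of Prok2 (2.29 ± 0.30), Snai1, a transcription factor gene best known from epithelial cells (1.65 ± 0.24), and Acod1, which makes itaconate (1.41 ± 0.23). S100a8 and S100a9 were steeper by 0.87 ± 0.10 and 0.87 ± 0.11 (SE, 9 libraries), Retnlg by 0.87 ± 0.11 and Cd14 by 1.11 ± 0.17. The formyl peptide receptors Fpr2 (0.84 ± 0.08) and Fpr1 (0.83 ± 0.09), C5ar1 (0.55 ± 0.09), Slc2a1 (0.36 ± 0.06) and the clock gene Per2 (0.45 ± 0.07) were called as well. Adjusted p-values of all these ran from 0.0254 for Fpr2 to 0.0481 for Slc2a1. Per2 stood at 10.4 CPM in Con, at 10.9, 19.2, 21.1 and 23.5 under SD, and at 7.71 to 10.4 under SASD.

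The rest of the named set were Olfm4 (1.07 ± 0.16), a marker of a neutrophil subset, Wfdc17 (1.27 ± 0.18), Wfdc21 (1.11 ± 0.12), Ifitm1 (1.07 ± 0.13) and Gm29264 (0.85 ± 0.12). Of the 18 genes of the SD trend 10 were among the 58, and 1071 genes had an unadjusted p under 0.05. Limma called 64 and DESeq2 1370 (363 with a higher and 1007 with a lower slope under SD). The calls fell to 0 without the 12 h or the 24 h libraries, to 1 without 48 h and to 18 without 6 h (13 of the 58), and reached 117 without Con. Linear hours gave 6. The edgeR adjusted p of S100a8 was 0.0629 without 6 h, 0.214 without 12 h, 0.234 without 24 h, 0.0398 without 48 h and 0.0635 with linear hours. Its slope difference stayed between 0.85 and 0.95 whichever time was left out. That of Fpr2 was 0.173 without 12 h, 0.234 without 24 h and 0.0922 without 48 h, and that of Prok2 0.214, 0.234 and 0.156. With the split as a term edgeR called 264 (258 steeper under SD), all 58 among them, and without Con and the 48 h libraries 0, with 1028 at an unadjusted p under 0.05.

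Gene lists were tested on this difference only after the data had been seen, and 17 of 29 passed camera, none (0) with an estimated correlation. Mature neutrophil genes were steeper under SD (1.58e-36, and adjusted p = 0.0572 with an estimated correlation; fry 0.00315), 9 over all genes and 22 of 22 adjusted over the list alone, with Ly6g at 1.17 ± 0.20 and Il1r2 at 0.96 ± 0.17. Granule and precursor genes (4.48e-14, and adjusted p = 0.137; fry 0.0255) gave 1 and 14 of 16, with Lcn2 at 0.92 ± 0.19, Mmp8 at 0.74 ± 0.13, Camp at 1.75 ± 0.47 and Mpo at 1.82 ± 0.52. Recruitment and adhesion (3.87e-13, and adjusted p = 0.182) gave 4 and 10 of 19, with Cxcr2 at 0.58 ± 0.12. Cytokine receptors and decoys (2.53e-11, and adjusted p = 0.137) gave 0 and 7 of 25, Il1rap standing at 0.67 ± 0.13. Cytokines and chemokines (8.49e-04, and adjusted p = 0.184) gave 0 and 4 of 24, with Il1b at 0.67 ± 0.13 and Osm at 0.49 ± 0.09.

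Glucocorticoid-induced genes (7.26e-07, and adjusted p = 0.220 with an estimated correlation, 22 of 22 above 0) were steeper under SD, with Dusp1 at 0.65 ± 0.20, as were glycolysis and hypoxia (2.20e-07, and adjusted p = 0.182), the NF-kB response (2.38e-04, and adjusted p = 0.257) and immediate early genes (1.60e-04, and adjusted p = 0.420). B cell genes had lower slopes under SD (1.77e-07, and adjusted p = 0.182, 0 of 18 above 0), with Pax5 at -0.28 ± 0.10, and so had MHC class II genes (0.00401, and adjusted p = 0.420), with Ciita, their transactivator, at -0.18 ± 0.04. Oxidative stress (2.38e-04, and adjusted p = 0.182), ribosomal proteins (2.92e-04, and adjusted p = 0.568), T cells (0.00107, and adjusted p = 0.568), coagulation and complement (0.00691, and adjusted p = 0.257) and proliferation (0.0131, and adjusted p = 0.568) were steeper. Without 48 h the calls of MHC class II (0.323), oxidative stress (0.0619), ribosomal proteins (0.323) and coagulation (0.323) ended and those of T cells (0.388) and proliferation (0.099997) turned. NK genes had lower slopes under SD (0.0264, and adjusted p = 0.502 with an estimated correlation), which ended without 6 h (0.109), 12 h (0.101) or 48 h (0.112). The clock list did not pass (0.776), and Nfil3 stood at 0.55 ± 0.10 with an edgeR adjusted p of 0.0634.

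The SD 48 h and SASD 48 h libraries lay on the side of Con and were each set against it. In SD 48 h Prok2 was 190.0 times Con (73.5 to 701.3), Mpo 61.8 times (37.6 to 109.1), Wfdc17 52.7 (44.4 to 62.9), Ngp 51.6 (45.9 to 58.2), Camp 49.98 (37.7 to 67.5), Upp1 46.2 (27.6 to 83.5), Ltf 34.8 (30.9 to 39.3), Ly6g 30.0 (22.8 to 40.2), Cd14 23.1 (18.8 to 28.8) and Prtn3 22.0 times (14.4 to 34.95). In SASD 48 h the Fc receptor gene Fcgr1 stood at 6.49 times Con (5.30 to 8.02), Ms4a6d at 3.61 (2.94 to 4.44), Siglec1 at 3.54 (2.90 to 4.34) and Chil3, a member of the granule and precursor list, at 3.48 (3.35 to 3.61). Fcgr1 was about as high in SD 48 h, at 20.3 CPM against 22.0 in SASD 48 h and 3.39 in Con. Sdc3, Tppp3, Mcub, Ifi205 and Gpr35 stood at 3.45 to 4.59. The monocyte median over Con was 0.60 in SD 48 h, 1.04 in SASD 48 h and 0.83 in SASD 120 h, and the mature neutrophil median 2.44, 0.15 and -0.07. Earlier, across the split, the mature neutrophil median was 0.37, 1.31 and 1.76 in SD 6, 12 and 24 h. In SASD 6, 12 and 24 h it was 0.45, -6.86e-05 and 0.47. Among matched random lists these SASD medians lay at percentiles of 99.77, 17.42 and 99.58.

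The genes lowest against Con included matrix genes such as Col12a1 and Col1a2, though no list of matrix genes was tested. In SD 48 h Slit2, Col12a1, Adamtsl3, Plet1, Slc4a10, Tnxb, Zan, Eps8l2, Col1a2 and Tmtc1 lay at ratios of 0.0673 to 0.166, and in SASD 48 h Ston1, Slit2, Ltbp4, Col3a1, Ildr2, Bmp2, Trim10, Col1a2, Slc4a10 and Ccn3 at 0.108 to 0.237. Olfactory receptor genes, which were detected at 53.1% in Con, went the same way. In SASD 120 h, on the other side of the split, high genes were Hba-a1 at 7.31 times Con, Fcgr1 at 5.51 (4.35 to 7.02), Paqr9 at 5.47, Rsad2 at 5.45, Hbb-bs at 4.99, Apol11b at 4.86, Ifi211 at 4.70, Hbb-bt at 4.70 and Hba-a2 at 4.61. Its lowest were Col12a1 with 2 counts (ratio 0.0181, 0.00219 to 0.0660), Alb, Clstn3, Eps8l2 and Slit2 with 3 counts each (0.0383 with 0.00784 to 0.113, 0.0396 with 0.00810 to 0.117, 0.0425 with 0.00870 to 0.126 and 0.0461 with 0.00943 to 0.137), and Ank2, Adamtsl3, Ttn, Slc47a1 and Igfbp5 at 0.0490 to 0.0905.

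Genes at 2-fold or more from Con numbered 1470, 1936, 1891 and 1676 in SD 6, 12, 24 and 48 h and 1690, 1662, 2280, 1202 and 1398 in SASD 6, 12, 24, 48 and 120 h. Pairs of libraries across the split differed at a median of 1419 genes (479 to 2280, 21 pairs), pairs on the same side at 447 (73 to 1676, 24 pairs). In SASD 48 h 212 genes were higher and 990 lower than in Con, and in SD 48 h 603 and 1073. With a mean count of at least 100 the counts fell to 433, 806, 814 and 581 and to 683, 549, 1029, 337 and 363. The excess of lower genes was then gone, with 176 higher and 161 lower in SASD 48 h and 470 and 111 in SD 48 h.

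The likeness of the changes was measured across genes, which are not independent replicates. Log2 ratios to Con in SD and SASD correlated with r of 0.81 at 6 h, 0.78 at 12 h, 0.70 at 24 h and 0.47 at 48 h, where unchanged groups simulated against the same Con library gave 0.43, 0.42, 0.41 and 0.47. Covariances were 0.325, 0.363, 0.395 and 0.123 against simulated 0.0773, 0.0776, 0.0771 and 0.0794. The single Con library cannot be divided, so part of the excess may come from it, and at 6, 12 and 24 h both ratios also crossed the split.

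In GENCODE release 21 of the mouse series, on mm10, S100a8 lies on chromosome 3 from 90668978 to 90670035. S100a9 lies from 90692632 to 90695721 on the same chromosome. Prok2 lies on chromosome 6 (99711299 to 99726392), Ngp, Ltf and Camp on chromosome 9 (110419747 to 110423012, 111019271 to 111042767 and 109847379 to 109849617), and Mmp8 there too (7558456 to 7568485). Il1b lies on chromosome 2 (129364570 to 129371139), Il1r2 on chromosome 1 (40074079 to 40125231), Fpr1 and Fpr2 side by side on chromosome 17 (17876471 to 17883940 and 17887824 to 17893952), Cd14 on chromosome 18 (36725067 to 36726798) and Per2 on chromosome 1 (91415982 to 91459324). Fcgr1 lies on chromosome 3 (96282909 to 96293969) and Hspa8 on chromosome 9 (40800984 to 40810087). All of these are annotated as protein-coding.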

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

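The difference between the trends gave 58 genes called by edgeR. Slopes under SD minus SASD were 2.29 for Prok2, 1.65 for Snai1, 1.41 for Acod1, 1.27 for Wfdc17, 1.11 for Cd14, 1.11 for Wfdc21, 1.07 for Ifitm1 and 1.07 for Olfm4. They were 0.87 for Retnlg, 0.87 for S100a8, 0.87 for S100a9 and 0.85 for Gm29264. Of the 17 lists that passed camera 0 passed with an estimated correlation. Their median slope differences were 0.66 for mature neutrophils, 1.02 for neutrophil granules and precursors, 0.30 for recruitment and adhesion, 0.20 for glucocorticoid-induced genes, 0.17 for proliferation, 0.16 for cytokine receptors and decoys and 0.13 for immediate early genes. The smaller ones were 0.105 for glycolysis and hypoxia, 0.0854 for T cells, 0.0874 for cytokines and chemokines, 0.0806 for the NF-kB response, 0.0837 for ribosomal proteins, 0.0739 for oxidative stress, 0.0630 for coagulation and complement, -0.0631 for NK cells, -0.0614 for MHC class II and -0.12 for B cells.

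The tests of depth and duration below were chosen only after the result was seen. Con and both 48 h libraries stood apart from the other 7 in haemoglobin and olfactory receptor counts. The highest haemoglobin share of the 3 was 0.204 times the lowest of the 7, which depth does not produce in a share of counts. Duration was left open: both methods rose from Con to 6 h and fell from 24 h to 48 h by at least 5.32 percentage points, and the libraries of a time lay on the same side. At 120 h the SASD share stood at 3.57%. Background from genomic DNA might give counts that rise with exon length, but the lowest Spearman rho of the 3 libraries, in SD 48 h, was 0.215, between the bounds set for and against it, and left this open for the 3 as a set. Con at 0.379 and SASD 48 h at 0.336 lay past the bound set for it, and the other 7 libraries at 0.0356 to 0.129.

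The tests of the split and of other cell types were chosen only after the result was seen, and that of the spread of members before. Mature neutrophil genes had rising slopes as a list under SD and higher slopes than under SASD (camera adjusted p = 0.254 and 0.0572 with an estimated correlation), and 6 of the 22 list genes also belong to another list. Within the split, the lowest median of SD over SASD at 12, 24 and 48 h was 1.26 (95% bootstrap interval over genes 1.09 to 1.55). The test left out 6 h, where the median was 0.12. By construction none of these ratios crossed the split, so crossing it could not make the difference at 12, 24 and 48 h. The medians are part of the pattern itself, so the test could not decide its cause. The slopes used libraries from both sides of the split. The interval covers the spread over genes of single pools, not that between pools. A loss of other leukocytes would raise alike all cell types that were not lost. At 48 h the neutrophil median of 2.16 exceeded the highest outside the neutrophils, 0.91 for platelets, by 1.25 (0.619 to 1.78, over genes of single pools). T cells stood at 0.60, erythroid cells at 0.52, NK cells at -0.08, monocytes at -0.25 and B cells at -0.48. The cell types thus did not rise alike, but the test could not exclude a loss of several types to different degrees. Whether more neutrophils or more transcript per neutrophil lay behind it was left open by an interquartile range of 1.35 (0.746 to 1.90) among members.

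The tests in this part were chosen only after the result was seen. Granule and precursor transcripts, of which 1 of 18 list genes also belongs to another list, had their highest median over Con in SD 48 h, 3.77, after 1.40 in SD 24 h and with 0.54 in SASD 24 h. The SASD 24 h median lay at a percentile of 99.95 among matched random lists, and that of SASD 48 h, 0.02, at 74.65. The SD 48 h median exceeded that of SASD 48 h, on the same side of the split, by 3.75 (2.53 to 4.82). This difference did not cross the split, but it is part of the pattern itself, so the test could not decide the cause. Its interval covers the spread over genes of single pools, not that between pools. Immature neutrophils in the blood were left open: the proliferation median of SD 48 h over SASD 48 h, 0.91, lay at the 100th percentile of matched random lists, but so did those of platelets and T cells, with erythroid genes at 99.96. With 1 pool of 3 mice, an event in a single animal could give the same result.

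The splits that part all 4 times were singled out only after the result was seen. For SD against SASD 3 of 35 splits could not be fitted with the time block, and with a real count of 0 genes 32 of 32 (highest other 1) reached it by construction, which says nothing on chance. As many unadjusted p-values under 0.05 came from 8 of 32 splits (real 1082, highest other 1680) and as many lists from 12 of 32 (real 15, highest other 20), so chance was not excluded for these counts. For the difference between the trends 7 of 35 splits gave as many lists (real 17, highest other 19), so chance was not excluded for these. The real split alone, 1 of 35, gave 58 genes (highest other 22), but the libraries are matched by time and only 8 splits part all 4 times. Of these 1 of 8 gave 58 genes (highest other 22) and 2 of 8 as many lists (highest other 18). For SD against SASD 2 of 8 gave as many unadjusted p-values (highest other 1357) and 2 of 8 as many lists (highest other 16). The 0 genes were reached by 8 of 8 (highest other 0) by construction. These are too few splits for a share under 0.05. For the SD trend 6 of 60 orders gave as many genes (real 18, highest other 346), so chance was not excluded. The 5 orders with 259 to 346 genes all set Con and SD 48 h apart from the other 3 libraries, a structure of the samples. With the split as a term 1 of 12 orders within the split reached the real 796 (highest other 779, the reversed order), too few orders to exclude chance.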

How the results depend on the processing

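No analysis paired by animal or replicate was possible because each group had 1 library and the groups share only the replicate number 1. SD and SASD were matched by time alone, with time as the block. Without the time block edgeR also called 0 genes, with 770 and not 1082 at an unadjusted p under 0.05. For SD against SASD the 0 called genes became 389 with no count minimum, 173 with DESeq2 and 0 to 237 with single times left out. The 18 genes of the SD trend became 63 with no count minimum, 431 with DESeq2, 50 with limma, 0 with linear hours, 65 with ranked times and 0 to 511 with single libraries left out. For SASD the 0 stayed at 0 to 1 with single libraries left out. The 58 genes of the difference became 88 with no count minimum, 1370 with DESeq2, 6 with linear hours and 0 to 117 with single times left out. Fits chosen after seeing the data gave 796 (split as a term), 638 (split with DESeq2) and 314 (without Con and 48 h) for SD, 113 (split with DESeq2) for SASD, and 264, 441 and 0 for the difference. An estimated correlation left 0 of 15, 19, 9 and 17 lists, and 0 for the 3 trends with the split as a term. With single libraries left out, lists numbered 13 to 16 for SD against SASD, 15 to 20 for SD, 5 to 11 for SASD and 14 to 18 for the difference. Directions turned without 48 h for T cells in SD against SASD (0.274, with 3.07e-04 as the lowest adjusted p) and for T cells (0.388, lowest 1.39e-06) and proliferation (0.099997, lowest 3.03e-07) in the difference. In the SD trend they turned without SD 48 h for proliferation (0.341, lowest 1.92e-06), ribosomal proteins (0.454, lowest 5.05e-09) and Camp (slope -0.21, highest 3.92 without Con). There, interferon-stimulated genes turned without Con (0.0347), over a range of 1.18e-07 to 0.0852. With a mean count of at least 100, genes at 2-fold from Con fell to 433, 806, 814 and 581 for SD and to 683, 549, 1029, 337 and 363 for SASD, and those of SD over SASD to 17, 216, 497 and 379. Higher and lower genes against Con were then 470 and 111 in SD 48 h and 176 and 161 in SASD 48 h, in place of 603 and 1073 and of 212 and 990. The correlation of SD and SASD changes at 6 h rose to 0.884 at that minimum, and its simulated value from 0.434 to 0.472. The covariance above the simulated one fell from 0.248 to 0.191. Of gene results with single libraries left out 343 stayed the same, 40 grew stronger, 100 weaker and 1 turned, and of list results 240, 48 weaker and 6 turned. The same meant 1 sign and 1 side of the threshold, so the 343 include genes that were called in neither fit. All 100 weaker gene results were called genes that lost their call, so these counts do not show that the called genes were stable. The cause of these shifts was not tested, apart from the minimum counts, which by construction remove weakly counted genes. Depth, from 7825120 to 27501393 counts, limits what can be said of genes under about 1 CPM, such as Prok2 in Con, SD 6 h and all SASD libraries.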

Other observations

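At 12 h genes induced by glucocorticoids stood high in both methods, among them Fkbp5, a cochaperone of the glucocorticoid receptor, and Ddit4, an inhibitor of mTOR. Fkbp5 was at 75.4 CPM in Con, at 74.4, 148, 76.6 and 119.8 under SD at 6, 12, 24 and 48 h, and at 91.4, 121, 59.8, 40.4 and 35.2 under SASD at 6, 12, 24, 48 and 120 h. Ddit4 was at 77.5 in Con, at 166 in SD 12 h and 154 in SASD 12 h, and at 54.6 and 58.6 at 6 h. Tsc22d3, or GILZ, was at 633 in Con, 1039 in SD 12 h and 942 in SASD 12 h, and the clock gene Per1 at 49.0, 113 and 78.5. This peak was picked out after the values were seen. Both methods reached 12 h at the same distance from the start, and the hour of the day of collection is not given in the sources used here.

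Ccr2 was at 138 CPM in Con, 524 in SD 24 h, 509 in SD 48 h, 73.4 in SASD 12 h and 419 in SASD 48 h, and Fcgr1 at 3.39, 26.9, 20.3, 3.58 and 22.0 in the same libraries. Isg20, an antiviral exonuclease, and the mitotic gene Nusap1, also picked out after their values were seen, followed haemoglobin: Isg20 was at 19.6 to 40.4 CPM in Con and both 48 h libraries and at 173 to 603 in the other 7, and Nusap1 at 3.38 to 6.75 and 22.3 to 66.0. Tnf stayed between 0.918 and 6.56 CPM in all 10 libraries while Il1b reached 479 in SD 12 h.

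Hypothesis: SD releases neutrophils from the bone marrow, mature cells by 12 h and immature cells by 48 h, and SASD does so to a smaller degree or not at all. It would be tested by blood counts with flow cytometry for Ly6G and CXCR2 in single mice at 12, 24 and 48 h. Hypothesis: the 12 h peak of Fkbp5 and Tsc22d3 reflects corticosterone at that hour. It would be tested by hormone measurements and by undisturbed controls taken at each hour. Hypothesis: Con and both 48 h libraries were prepared apart from the rest, with other removal of red cells or DNA. It would be tested against preparation dates and by a second preparation of stored RNA.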
